A study of Mus musculus with 41 samples.

How the data were processed

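The samples were FLAG ChIP-seq libraries of tagged Runx2 from rib chondrocytes and calvarial osteoblasts of newborn mice, Foxa2 ChIP-seq of rib chondrocytes, Jun ChIP-seq of calvarial osteoblasts, and FLAG ChIP-seq of 3T3 fibroblasts expressing tagged Runx2 or GFP at day 0 and day 3 of osteogenic medium. Input libraries, the IgG control and the 23 ATAC-seq libraries were not analysed here. The authors deposited 1 peak list for each of the 8 ChIP groups. Each list gave the chromosome, start and end of its peaks in 3 columns, with no score, height or p-value, as the deposited files show. The genome build was mm9, and Bowtie and DiffBind were used at steps that are not named, per the submitters' processing notes. The peak caller, its threshold, the control used for each list and all versions were not given in the sources used here. Nor was it given whether the 2 Runx2 libraries of each primary cell type were pooled before their single list was made. Read depth was likewise not given, so no test was made of list sizes.

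Groups followed the labels. For 2 of the 4 lists of 3T3 cells the labels were crossed: the list named for GFP day 3 was tied to the Runx2 day 0 sample, and the list named for Runx2 day 0 to the GFP day 3 sample. These lists were used under their own names throughout, and exchanging them was an alternative. The 1271 peaks that lay beyond the last gene of the GRCm38 annotation (875 of them on chromosome 7) showed that the coordinates were not of that build. Coordinates are printed 1-based in mm9 as deposited. The gene table at hand was of another build and no genome sequence was at hand, so the planned shares near gene lists, at promoters and with RUNX, AP-1 or FOX motifs were not run. Of each list and class, the regions named are among the 3 widest (ties taken by position), a rule set before the data were examined for files without a score.

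A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Shares have Wilson 95% intervals. The chance value was the mean over 1000 circular shifts of 1 list within each chromosome, with a one-sided permutation p. A second chance value, chosen after seeing the data, moved each peak separately by 5 to 50 kb. Classes of peaks (chondrocyte-only, shared and osteoblast-only Runx2; day 0 only, both days and day 3 only in 3T3 cells) were compared by two-sided Fisher's exact tests with conditional odds ratios, and p-values below 1e-300 were set to that value. The difference in share was also computed on each of 20 chromosomes and tested with a two-sided sign-flip permutation test (100000 resamples). The 49 class tests were adjusted together by the Benjamini-Hochberg method, and 44 had an adjusted p under 0.05. Among them 2 repeat another table read from the other side (Foxa2 or Jun by sharing between the primary cell types), and each such table is reported once. Peaks of a class that is defined by a list were not tested against that list.

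Overlap counts were checked against bedtools 2.31.1, with 0 of 56 pairs differing. On simulated overlaps for the 10782 chondrocyte-only and 5616 osteoblast-only peaks, 97 of 100 intervals held a planted odds ratio of 1, 97 of 100 one of 1.5 and 94 of 100 one of 3, with 3, 100 and 100 of 100 draws called. Of 60 pairs of unrelated simulated lists, 0 were called by the shift test. The first simulation drew counts of overlapping peaks at a fixed base share and placed no peaks. The second placed peaks independently of each other and used fewer shifts than the tests reported here. Neither covers the clustering of the real peaks, and the first does not cover an odds ratio as high as that of Foxa2. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

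Alternatives set in advance were overlap of at least 50% of the shorter peak, centres within 250 bp, the wider 50% of each list, lists reduced at random to equal size, removal of peaks overlapping a GFP list, exchange of the crossed lists, removal of sex chromosomes, and chromosomes as units. Those added after seeing the data were the first 50% of each list in file order, all peaks set to 200 bp around their centres, overlapping peaks merged, local moves as chance, Mantel-Haenszel odds ratios over 10 equal parts of each list in file order, classes without peaks overlapping a GFP list (both lists by name, GFP day 0 alone, or both after the exchange), and the list named for GFP day 3 reduced at random to the size of GFP day 0. File order was used because early peaks recurred in other lists more often in the pairs examined, except for osteoblast Runx2 peaks in the Foxa2 list. The sources used here do not say how the files were ordered.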

Results

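The series mapped where Runx2, the transcription factor required for osteoblast formation, sat in the chromatin of mouse skeletal cells and of a fibroblast line given the factor. It comprised 41 samples in 24 groups: 23 ATAC-seq libraries of open chromatin, 10 chromatin immunoprecipitation (ChIP-seq) libraries, 7 input libraries and 1 IgG control. Runx2 was precipitated through a FLAG tag, with 2 libraries from rib chondrocytes and 2 from calvarial osteoblasts of newborn knock-in mice at postnatal day 1. Foxa2, a forkhead transcription factor, was precipitated from wild-type rib chondrocytes (1 library), and Jun, a subunit of the AP-1 factor, from wild-type calvarial osteoblasts (1 library). The same FLAG precipitation was applied to 3T3 mouse fibroblasts expressing tagged Runx2 or green fluorescent protein (GFP) as the background control, at day 0 and after 3 days in an osteogenic medium with ascorbate, glycerophosphate and 100 ng/ml BMP-2 (1 library each). The comparisons used 8 peak lists with 155773 peaks in all. The ATAC-seq data were not analysed here, and sequencing depth was not given in the sources used here.

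Each group was represented by 1 list, so no value has a replicate error. Intervals are 95% Wilson intervals for shares and conditional 95% intervals for odds ratios. They cover counting error only, and neighbouring peaks are not independent. For that reason each difference between peak classes was also tested over 20 chromosomes by a two-sided sign-flip permutation test, whose smallest p with 100000 resamples was 1e-05. Neither test measures the spread between animals or cultures. All chondrocyte lists came from rib and all osteoblast lists from calvaria, so cell type cannot be told apart from skeletal site.

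The lists differed widely in size. Chondrocyte Runx2 had 15390 peaks (median width 136 bp), osteoblast Runx2 10241 (186 bp), chondrocyte Foxa2 14738 (120 bp) and osteoblast Jun 14937 (134 bp). In 3T3 cells the list named for Runx2 day 0 had 31013 peaks (190 bp) and Runx2 day 3 had 50180 (213 bp), against 2475 (203 bp) for GFP day 0 and 16799 (254 bp) for the list named for GFP day 3. By these names the Runx2 list was 12.5 times the size of the GFP list at day 0 and 2.99 times at day 3. The labels of the lists named for Runx2 day 0 and GFP day 3 were crossed, and with these exchanged the ratios were 6.79 and 1.62. Foxa2 had the most private list: 72.8% of its peaks (72.1 to 73.5%) overlapped none of the other lists, against 40.6% for Jun (39.9 to 41.4%), 21.3% for chondrocyte Runx2 (20.6 to 21.9%) and 21.7% for osteoblast Runx2 (21.0 to 22.6%).

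All 56 ordered pairs of lists overlapped more than expected by chance. The excess over 1000 circular shifts ranged from 2.67-fold, for the share of the list named for GFP day 3 that overlapped Foxa2, to 199-fold, for osteoblast Runx2 peaks within the chondrocyte Runx2 list. Each pair had a one-sided permutation p of 0.001, the smallest the shifts can give, and an adjusted p of 0.001 over the 56 pairs (Benjamini-Hochberg). Against random moves of each peak by 5 to 50 kb, which keep the peaks in their neighbourhood, the excess ranged from 1.49-fold to 78.7-fold.

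**Figure D1:**
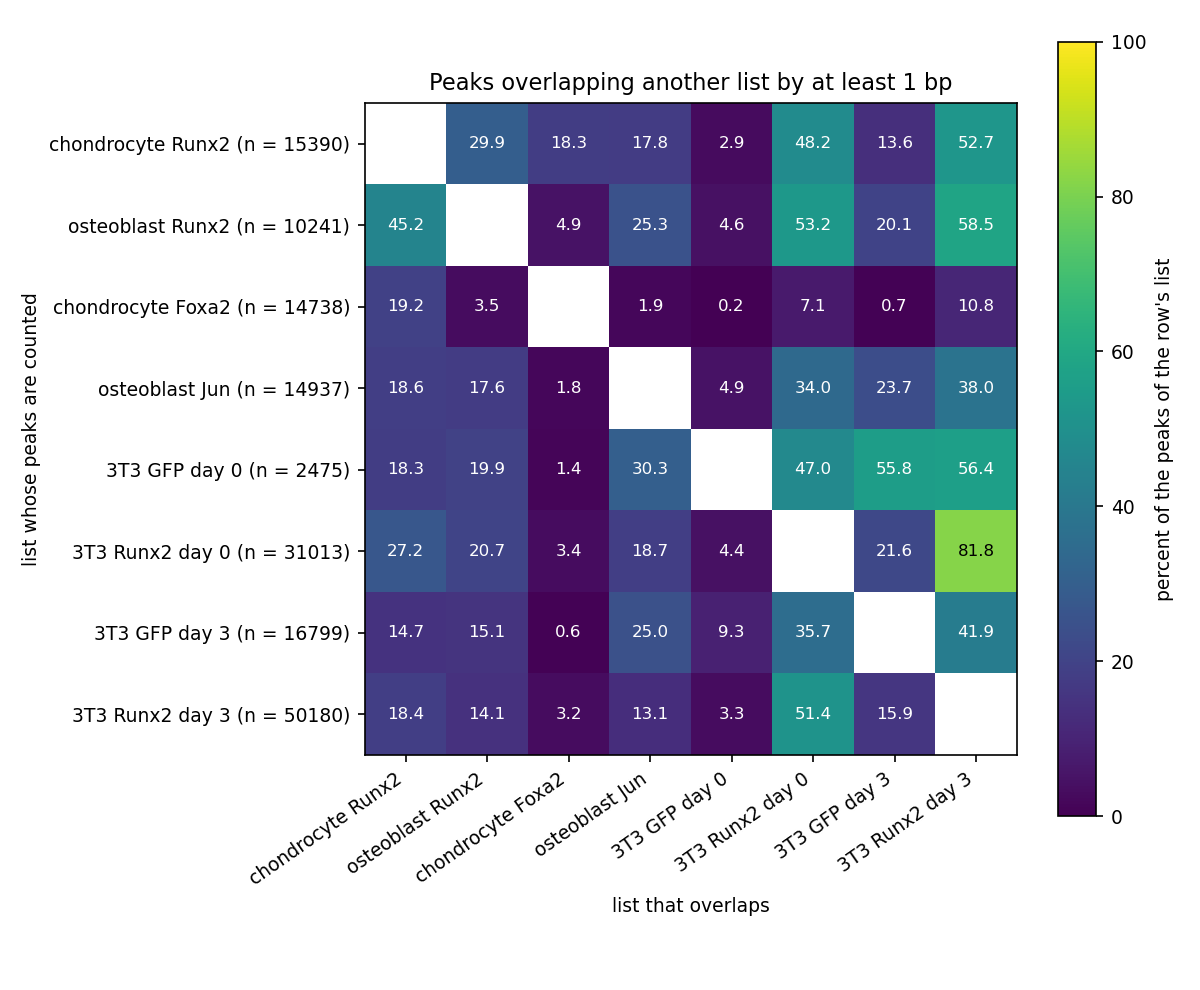
Percent of the peaks of each list (rows, with the number of peaks) that overlapped each other list (columns) by at least 1 bp, with colour giving the percent from 0 to 100. The 3T3 lists carry the names of their files. The highest share, 81.8%, was that of 3T3 Runx2 day 0 peaks in the day 3 list, and the row and column of Foxa2 held low shares outside chondrocyte Runx2.

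The first comparison asked how far Runx2 occupied the same sites in chondrocytes and osteoblasts. Of the chondrocyte peaks, 4608 of 15390 (29.9%, 29.2 to 30.7%) overlapped an osteoblast peak, and 4625 of 10241 osteoblast peaks (45.2%, 44.2 to 46.1%) overlapped a chondrocyte peak. This left 10782 chondrocyte-only and 5616 osteoblast-only peaks. Chance overlap from circular shifts was 0.151% of the chondrocyte peaks, with 0.253% as the highest of 1000 shifts. Where both lists were reduced to their wider 50%, the chondrocyte share fell to 13.8%, and in the first 50% of each list in file order it was 31.5%. A shorter list holds fewer possible partners, so the fall is not by itself an effect of width. The share also depended on the order of the file, from 68.5% in the first 1539 chondrocyte peaks to 7.41% in the last 1539, and from 71.5% in the first 1024 osteoblast peaks to 30.2% in the last 1025.

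The widest chondrocyte-only Runx2 peak lay on chromosome 15 from 50078278 to 50079159 (882 bp, build mm9) and overlapped Foxa2, Jun and both 3T3 Runx2 lists. The next widest lay on chromosome 17 from 44705988 to 44706484, overlapping Foxa2 and no other list, and on chromosome 19 from 53464842 to 53465338, overlapping both 3T3 Runx2 lists and the list named for GFP day 3. Among osteoblast-only peaks the widest lay on chromosome 8 from 114167512 to 114168027 (516 bp), and it overlapped Jun, both 3T3 Runx2 lists and the list named for GFP day 3. The 2 that followed were on chromosome 11 from 6314941 to 6315438 and on chromosome 18 from 55355893 to 55356390, and both overlapped the 3T3 Runx2 lists of both days, the former also the list named for GFP day 3. The widest shared peaks of the chondrocyte list lay on chromosome 2 from 136893316 to 136893813, chromosome 10 from 127104912 to 127105408 and chromosome 6 from 11857480 to 11857975. All 3 were also in both 3T3 Runx2 lists, and the last 2 overlapped Jun and the list named for GFP day 3 as well. In the osteoblast list the widest shared peaks lay on chromosome 17 from 85357361 to 85357858, chromosome 10 from 82557812 to 82558308 and chromosome 1 from 130255803 to 130256298, of which the first and last overlapped the list named for GFP day 3. A gene annotation of this build was not used here, so no gene is given for these positions.

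The second comparison asked whether Foxa2 in chondrocytes lay at the Runx2 sites of chondrocytes rather than those of osteoblasts. The share of Runx2 peaks overlapped by Foxa2 was highest in the chondrocyte-only class. Foxa2 overlapped 2416 of 10782 chondrocyte-only Runx2 peaks (22.4%, 21.6 to 23.2%), 402 of 4608 shared peaks (8.72%, 7.94 to 9.57%) and 103 of 5616 osteoblast-only peaks (1.83%, 1.51 to 2.22%). The odds of Foxa2 overlap were 15.5 times higher in chondrocyte-only than in osteoblast-only peaks (95% interval 12.6 to 19.1). Foxa2 was precipitated only from chondrocytes, so an effect of the factor cannot be told apart from one of the cell type. Shared peaks lay between the other classes, with an odds ratio of 0.331 against chondrocyte-only peaks (0.295 to 0.370; exact test, adjusted p = 1.01e-99) and of 5.09 against osteoblast-only peaks (4.08 to 6.41; exact test, adjusted p = 5.19e-59).

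Fisher's exact test of chondrocyte-only against osteoblast-only peaks gave the smallest p kept here, 1e-300. The share was higher in chondrocyte-only peaks on 20 of 20 chromosomes (sign-flip permutation p = 1e-05, the smallest it can give). The odds ratio was 7.17 in the wider 50% of each list, 7.14 in lists reduced at random to equal size and 24.7 in the first 50% of each list in file order. In shortened lists, shared peaks that lost their partner counted as private. At equal size 7194 peaks were osteoblast-only, against 5616 as deposited. Osteoblast Runx2 peaks early in the file overlapped Foxa2 less often (2.93% of the first 1024 peaks and 6.63% of the last 1025).

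Chondrocyte Runx2 peaks with Foxa2 were less often found in the Jun and 3T3 lists tested than those without it. Jun in osteoblasts overlapped 5.43% of the 2818 Runx2 peaks with Foxa2 against 20.6% of the 12572 without (odds ratio 0.221, 0.186 to 0.262; adjusted p = 4.30e-99, Fisher's exact test), and 3T3 Runx2 at day 3 28.5% against 58.1% (odds ratio 0.288, 0.263 to 0.315; adjusted p = 1.23e-180). The list named for GFP day 3 overlapped 0.816% (0.544 to 1.22%) against 16.5% (15.9 to 17.2%). Within the chondrocyte-only peaks the same contrast was 3.73% against 14.7% for Jun and 23.4% against 49.3% for 3T3 Runx2 at day 3. Each of these differences had the same direction on 20 of 20 chromosomes. From the other side, 2837 of 14738 Foxa2 peaks (19.2%, 18.6 to 19.9%) overlapped chondrocyte Runx2, 3.48% (3.20 to 3.79%) osteoblast Runx2 and 1.87% (1.66 to 2.10%) osteoblast Jun. The 3 widest Foxa2 peaks lay on chromosome 16 from 23993409 to 23993905, which overlapped 3T3 Runx2 day 3, on chromosome 18 from 3004595 to 3005091 and on chromosome 1 from 43992245 to 43992740, which overlapped no other list.

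**Figure D2:**
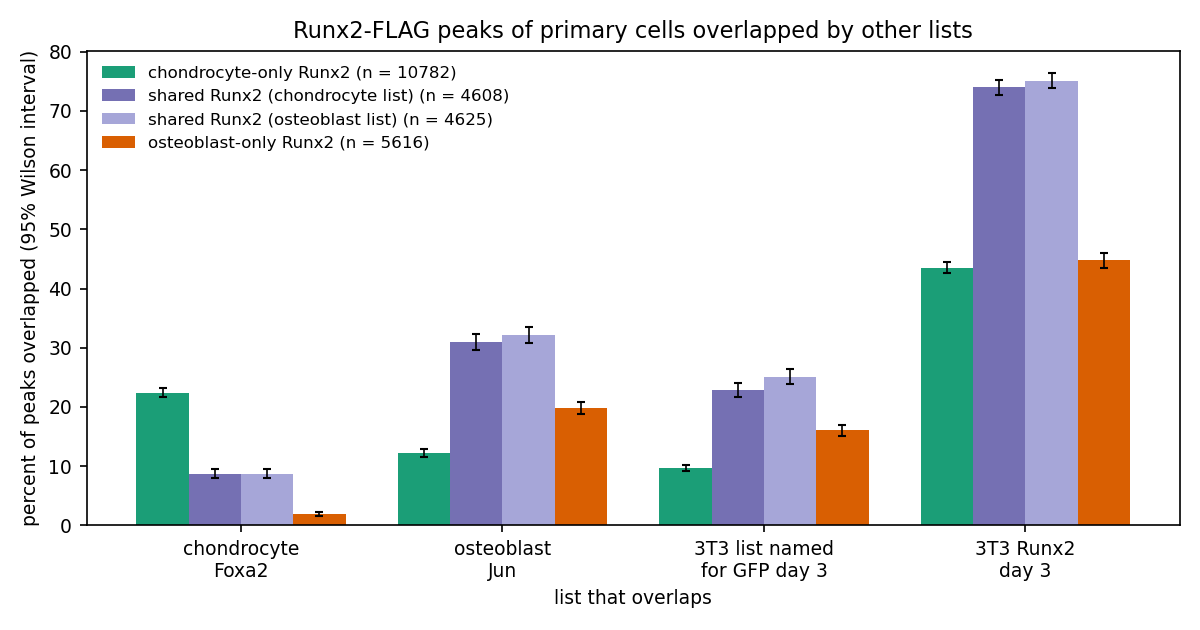
Percent of Runx2-FLAG peaks in primary cells overlapped by 4 other lists, by class of peak, with 95% Wilson intervals; shared peaks are counted in each of the lists they come from. Foxa2 overlapped 22.4% of chondrocyte-only and 1.83% of osteoblast-only peaks, whereas Jun and both 3T3 lists overlapped shared peaks most often.

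The third comparison put the same question for Jun in osteoblasts. Jun overlapped shared Runx2 peaks most often, osteoblast-only peaks less often and chondrocyte-only peaks least. It overlapped 1486 of 4625 shared peaks of the osteoblast list (32.1%, 30.8 to 33.5%), 1110 of 5616 osteoblast-only peaks (19.8%, 18.7 to 20.8%) and 1319 of 10782 chondrocyte-only peaks (12.2%, 11.6 to 12.9%). The odds ratio of osteoblast-only against chondrocyte-only peaks was 1.77 (1.62 to 1.93; Fisher's exact p = 1.00e-36, adjusted p = 1.33e-36). That of shared against osteoblast-only peaks was 1.92 (1.75 to 2.11; exact test, adjusted p = 4.57e-46). Jun was precipitated only from osteoblasts, so the contrast of osteoblast-only with chondrocyte-only peaks cannot separate the factor from the cell type.

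The share was higher in osteoblast-only than in chondrocyte-only peaks on 20 of 20 chromosomes and higher in shared than in osteoblast-only peaks on 19 of 20 (sign-flip permutation p = 1e-05 for both, the smallest it can give). The list named for GFP day 3, a background list only if its name is right, showed the same order. It overlapped 25.1% of shared peaks of the osteoblast list, 16.0% of osteoblast-only and 9.67% of chondrocyte-only peaks (odds ratio of osteoblast-only against chondrocyte-only 1.78, 1.62 to 1.96). With peaks that overlapped a GFP list removed from the classes, the Jun odds ratio was 1.73 (1.56 to 1.92). This removal used a list with crossed labels. With the GFP day 0 list alone it was 1.74 (1.59 to 1.91), and with the crossed lists exchanged 2.13 (1.86 to 2.44).

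Osteoblast Runx2 peaks with Jun (2596) recurred in the 3T3 lists tested more often than those without (7645). The shares in 3T3 Runx2 at day 3 were 71.4% and 54.1% (odds ratio 2.12, 1.92 to 2.34), and those in the list named for GFP day 3 were 34.6% and 15.2% (odds ratio 2.95, 2.66 to 3.27). Foxa2 went the other way, with 3.27% of the peaks with Jun and 5.49% of those without (odds ratio 0.582, 0.454 to 0.740; exact test, adjusted p = 3.97e-06). The share was higher with Jun on 4 of 20 chromosomes. Within osteoblast-only peaks the Foxa2 difference did not pass the exact test (1.53% against 1.91%, adjusted p = 0.474). From the first 1024 to the last 1025 osteoblast Runx2 peaks in file order, Jun overlap fell from 49.7 to 14.8%. Overlap with 3T3 Runx2 day 3 fell from 79.9 to 39.0%. The 3T3 contrasts by Jun were not compared within parts of the file order, so they cannot be told apart from file position. Among Jun peaks, 2633 of 14937 (17.6%, 17.0 to 18.2%) overlapped osteoblast Runx2 and 18.6% (18.0 to 19.3%) chondrocyte Runx2. The 3 widest Jun peaks lay on chromosome 15 from 36722325 to 36722822, chromosome 19 from 3575785 to 3576282 and chromosome 9 from 102527918 to 102528415, and the last of them was also an osteoblast Runx2 peak. The first and last overlapped the list named for GFP day 3.

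The fourth comparison set Runx2 in 3T3 fibroblasts against the GFP control of the same day. Of the peaks in the list named for Runx2 day 0, 1354 of 31013 (4.37%, 4.14 to 4.60%) overlapped the GFP day 0 list. At day 3, 7988 of 50180 Runx2 peaks (15.9%, 15.6 to 16.2%) overlapped the list named for GFP day 3. Counted from the control, 47.0% (45.0 to 49.0%) of GFP day 0 peaks lay in the list named for Runx2 day 0 and 41.9% (41.2 to 42.7%) of the peaks named for GFP day 3 lay in Runx2 day 3. Chance overlap of Runx2 peaks was 0.0461% at day 0 and 0.299% at day 3.

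The 2 lists with crossed labels were each tied to the sample of the other name. With these lists exchanged the shares were 9.29% at day 0 and 51.4% at day 3, and in the wider 50% of each list the share at day 3 was 8.86%. Shorter lists hold fewer possible partners, so the value in the wider 50% need not reflect width. With the list named for GFP day 3 reduced at random to the 2475 peaks of GFP day 0, the day 3 share was 2.80% on average over 100 draws (2.62 to 3.01%), against 4.37% at day 0. Random reduction lowers the share whatever its cause. The Runx2 lists also kept their unequal sizes (31013 peaks at day 0 and 50180 at day 3). These values therefore cannot tell why the days differed. Peaks named for GFP day 3 that were also in Runx2 day 3 (7044) overlapped primary-cell Runx2 more often than the other 9755, with 27.5% against 6.24% for osteoblast Runx2 (odds ratio 5.69, 5.16 to 6.28) and 28.0% against 5.15% for chondrocyte Runx2 (odds ratio 7.18, 6.46 to 7.98). For Jun the shares were 35.5% and 17.3% (odds ratio 2.63, 2.45 to 2.83). All 3 differences held on 20 of 20 chromosomes. They were not compared within parts of the file order. From the first 1679 to the last 1680 peaks named for GFP day 3, overlap with Runx2 day 3 fell from 57.9 to 19.3%. Overlap with Jun fell from 42.3 to 10.1%.

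The fifth comparison asked how Runx2 sites in 3T3 cells changed over 3 days in osteogenic medium. By the names of the lists, most day 0 peaks were also listed at day 3, and 24409 peaks were listed at day 3 only. Of the day 0 peaks, 25370 of 31013 (81.8%, 81.4 to 82.2%) overlapped a day 3 peak, while 25771 of 50180 day 3 peaks (51.4%, 50.9 to 51.8%) overlapped a day 0 peak. The peaks found at day 3 only were poor in sites of primary cells: 4.82% (4.56 to 5.10%) overlapped osteoblast Runx2, against 22.9% (22.4 to 23.5%) of day 3 peaks present on both days. The odds ratio was 0.170 (0.159 to 0.182), with a lower share at day 3 only on 20 of 20 chromosomes. Both properties followed file order. From the first to the last 5018 peaks of the day 3 list, the share also at day 0 fell from 95.7 to 14.5%. The share in osteoblast Runx2 fell from 50.2 to 2.89%. Compared within 10 equal parts of the list in file order, the contrast was weaker (Mantel-Haenszel odds ratio 0.497, 0.460 to 0.536).

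The same order held for chondrocyte Runx2 (6.65% against 29.6%, odds ratio 0.170, 0.160 to 0.180), Jun (5.53% against 20.3%, odds ratio 0.230, 0.216 to 0.245) and the list named for GFP day 3 (7.35% against 24.0%, odds ratio 0.251, 0.237 to 0.265). Foxa2 overlapped 3.15% of peaks at day 3 only and 3.33% of those on both days, and this difference did not pass the exact test (odds ratio 0.943, 0.853 to 1.04; adjusted p = 0.273). The 5643 peaks at day 0 only lay between, with 10.5% (9.74 to 11.3%) in osteoblast Runx2. The contrasts for chondrocyte Runx2, Jun and the list named for GFP day 3 were not compared within parts of the file order. The widest peaks at day 3 only were on chromosome 10 from 94495681 to 94496178, chromosome 12 from 71160055 to 71160552 and chromosome 12 from 111076079 to 111076576, and none of the 3 overlapped another list. The widest day 3 peak also present at day 0 was on chromosome 3 from 51144343 to 51145009 (667 bp) and overlapped Runx2 of both primary cell types, Jun and the list named for GFP day 3. At day 0 only, the widest were on chromosome 5 from 145877260 to 145877755, which overlapped Runx2 of both primary cell types, chromosome 13 from 28822020 to 28822514, which overlapped osteoblast Runx2, and chromosome 15 from 58764787 to 58765280, which overlapped the GFP day 0 list.

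The share of day 0 peaks kept at day 3 was 50.1% in the wider 50% of each list, 53.9% with the day 3 list reduced at random to the size of the day 0 list and 41.9% with the crossed lists exchanged, when 42192 peaks were at day 3 only. The odds ratio of osteoblast Runx2 overlap was 0.309 in the wider 50%, 0.379 with all 3 lists reduced at random to the 10241 peaks of the osteoblast list, 0.295 with the exchange, and 0.497 (0.460 to 0.536) when day 3 peaks were compared within 10 equal parts of the list in file order (Mantel-Haenszel). Shorter lists hold fewer possible partners. Shortening can therefore lower the kept share and move peaks from both days to day 3 only, whatever their width.

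**Figure D3:**
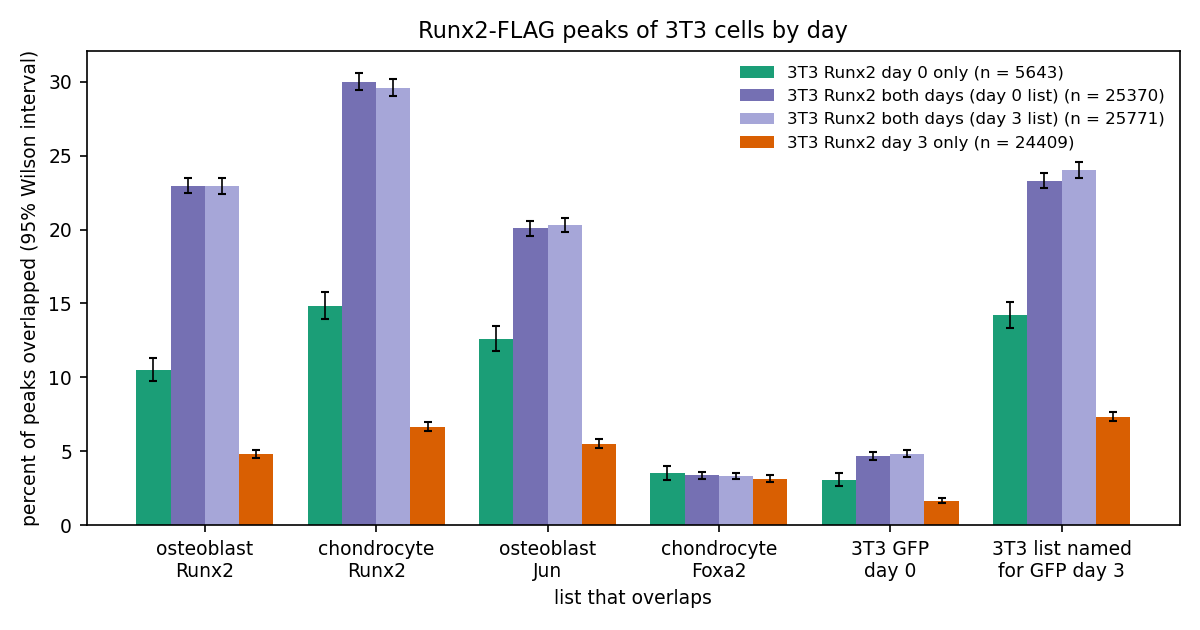
Percent of 3T3 Runx2-FLAG peaks found at day 0 only, on both days (counted in each day's list) or at day 3 only that overlapped 6 other lists, with 95% Wilson intervals. Peaks at day 3 only had 4.82% in osteoblast Runx2 and 6.65% in chondrocyte Runx2, below peaks on both days, while Foxa2 overlapped between 3.15% and 3.53% of every class.

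The sixth comparison asked whether the Runx2 sites of 3T3 cells resembled those of osteoblasts or of chondrocytes. In the lists as deposited, Runx2 in 3T3 cells at day 3 overlapped shared Runx2 peaks more often than the private peaks of either primary cell type. Sharing and day 3 overlap both fell in file order. From the first to the last 10% of peaks, day 3 overlap fell from 79.9 to 39.0% (osteoblast list) and from 70.8 to 33.0% (chondrocyte list). Sharing fell from 71.5 to 30.2% and from 68.5 to 7.41%. Shared and private peaks were not compared within parts of the file order, so this contrast cannot be told apart from file position. The day 3 list overlapped 2515 of 5616 osteoblast-only peaks (44.8%, 43.5 to 46.1%) and 4691 of 10782 chondrocyte-only peaks (43.5%, 42.6 to 44.4%), and 75.1% (73.9 to 76.4%) of the shared peaks of the osteoblast list. The odds ratio of osteoblast-only against chondrocyte-only peaks was 1.05 (0.986 to 1.12) and did not pass Fisher's exact test (p = 0.119, adjusted p = 0.130). For the list named for Runx2 day 0 the shares were 37.5% and 38.1% (odds ratio 0.977, 0.914 to 1.04; exact test, adjusted p = 0.508), with 72.3% (71.0 to 73.6%) of the shared peaks. With the crossed lists exchanged the day 0 call changed, since the list named for GFP day 3 overlapped 16.0% of osteoblast-only and 9.67% of chondrocyte-only peaks (odds ratio 1.78, 1.62 to 1.96; exact test, adjusted p = 1.31e-31; higher on 19 of 20 chromosomes) and 25.1% of the shared peaks.

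The call at day 3 depended on the setting. The difference passed the test in the wider 50% of each list (odds ratio 1.12; 27.2% of osteoblast-only and 25.0% of chondrocyte-only peaks), at equal list size (1.25; 12.1% and 9.95%), in the first 50% in file order (1.24; 50.9% and 45.5%), without class peaks overlapping a GFP list after exchange of the crossed lists (1.15; 20.2% and 18.0%) and over chromosomes (median difference 0.845 percentage points, sign-flip permutation p = 0.0416), and the odds ratio lay below 1 with peaks of 200 bp around their centres (0.975) and without peaks of the classes that overlapped a GFP list by its name (0.998). At equal size the chondrocyte list was thinned, and shared peaks that lost their partner entered the osteoblast-only class (7194 peaks, against 5616 as deposited). Shared peaks overlapped the day 3 list most often, so this setting raises the odds ratio by itself. It cannot show an effect of list size.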

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

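The test of chromosome Y clustering was chosen after its result was seen, as were the chromosome 15 contrast and the equal-size comparison of GFP lists.

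The chondrocyte Foxa2 list held 46 peaks on chromosome Y, which is outside the 20 chromosomes on which class differences were tested, against 2 in the Jun list and 0 in each of the other 6 lists. Of these, 43 lay between 2779905 and 2901693 (122 kb, mm9), where no other list had a peak. That 93.5% fell within 150 kb suggests a single stretch, such as a repeat or an amplified segment, rather than sites along the chromosome. A control library with another mix of sexes could also leave an excess on chromosome Y, and was predicted to come with a lower chromosome X share. The odds of a chromosome X peak were 1.37 times higher in the Foxa2 list than in the chondrocyte Runx2 list (1.11 to 1.70). These lists differ in factor and in animals, so the comparison cannot decide on the control. Foxa2 binding to that stretch stays open, since read coverage and the IgG control were not analysed here.

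The share of Runx2 peaks in 3T3 cells that overlapped the GFP list of the same day differed between days, from 4.37% at day 0 to 15.9% at day 3 (odds ratio 4.15, 3.91 to 4.40, Fisher's exact test of the difference), and it was higher at day 3 on 20 of 20 chromosomes. The list named for GFP day 3 was 6.79 times the size of GFP day 0. With that list reduced at random to the 2475 peaks of day 0, the day 3 share was 2.80% on average over 100 draws (2.62 to 3.01%). Random reduction lowers the share whatever its cause, and the Runx2 lists kept their unequal sizes. The fall therefore cannot tell why the days differed. With the crossed lists exchanged, the odds ratio was 10.3 (9.75 to 10.9).

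Chromosome 15 held 6.18% of the peaks of the list named for Runx2 day 0 and 6.02% of GFP day 0 (odds ratio 1.03), but 6.38% of Runx2 day 3 and 4.72% of the list named for GFP day 3 (odds ratio 1.38). The ratio of these odds ratios was 1.34 (95% interval 1.11 to 1.62 on the log scale, over peaks, which are not independent). Exchanging the crossed lists leaves this ratio in place, since it is built from the same 4 lists. The interval is not adjusted for the choice of chromosome. Chromosome 11 also differed, with 9.53% of the list named for Runx2 day 0 and 13.0% of GFP day 0. At day 3 it held 9.12% of Runx2 and 9.34% of the list named for GFP day 3.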

How the results depend on the processing

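Of 99 alternative values of tested results, 92 kept the direction and the side of the threshold. For overlap shares this required only a value above chance overlap, so it does not show that their size was stable. The 7 values that did not keep both all concerned the odds ratio of 3T3 Runx2 day 3 overlap between osteoblast-only and chondrocyte-only peaks (1.05 as deposited). It passed the threshold in the wider 50% of each list (1.12), at equal list size (1.25), over chromosomes as units (0.845 percentage points), in the first 50% in file order (1.24) and without class peaks overlapping a GFP list after exchange of the crossed lists (1.15). It lay below 1 with all peaks set to 200 bp (0.975) and without class peaks overlapping a GFP list by its name (0.998), in neither case past the threshold. At equal list size shared peaks entered the osteoblast-only class (7194 peaks, against 5616 as deposited), which by itself raises this odds ratio. The cause of the other changes was not tested. The 2 settings with values below 1, the file-order setting and the exchange with removal were chosen after seeing the data.

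Across alternatives the share of chondrocyte Runx2 peaks shared with osteoblasts ranged from 13.8 to 31.5%, the share of 3T3 Runx2 day 0 peaks kept at day 3 from 41.9 to 87.2%, the share of 3T3 Runx2 peaks in the GFP list from 3.01 to 9.29% at day 0 and from 2.78 to 51.4% at day 3, the odds ratio of Jun overlap from 1.68 to 2.13, that of Foxa2 from 7.14 to 24.7 and that of day 3 only against both days from 0.158 to 0.497 (odds ratio settings only). The lowest GFP share at day 3 came from the GFP list reduced at random to the size of GFP day 0, chosen after seeing the data. The 16 alternative numbers of peaks, which have no test, stayed within 1.5 times under merging and removal of peaks in all 8 lists. No paired analysis was possible because the 2 replicates of a Runx2 group were represented by 1 list, and leaving out replicates could not be run for the same reason. Gene list, promoter and motif alternatives were not run for want of an mm9 reference. The lists give no depth, so a peak missing from a list is not shown to be unbound.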

Other observations

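The windows below were chosen after their values were seen, as were both tests of the crossed labels, the direct overlaps beside them and the 2 other choices of GFP lists for Jun. The first 2 tests of Jun at shared sites were set before their results.

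Some stretches of the genome held many private Runx2 sites. The 200-kb window with the most chondrocyte-only Runx2 peaks lay on chromosome 7 from 86000001 to 86200000, with 18 such peaks, 15 Foxa2 peaks, 0 Jun peaks and 4 osteoblast Runx2 peaks. The next windows did hold Jun peaks. That on chromosome 2 from 32600001 to 32800000 had 14 chondrocyte-only peaks, 3 Foxa2 peaks and 7 Jun peaks. The window on chromosome 1 from 92600001 to 92800000 had 12, 10 and 8. For osteoblast-only peaks, windows on chromosome 11 from 94600001 to 94800000 and from 98800001 to 99000000 each held 12. The former had 17 Jun peaks, 2 Foxa2 peaks and 1 chondrocyte Runx2 peak, and the latter 9 Jun peaks, 3 Foxa2 peaks and 5 chondrocyte Runx2 peaks. A window on chromosome 10 from 66400001 to 66600000 held 9, with 11 Jun peaks, 8 Foxa2 peaks and 6 chondrocyte Runx2 peaks. Shared peaks were most numerous on chromosome 15 from 77000001 to 77200000, with 8 in the chondrocyte list beside 11 Jun peaks and 31 peaks of 3T3 Runx2 day 3.

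All lists were clustered more than their own peaks moved by 5 to 50 kb. The share of peaks with at least 2 neighbours within 10 kb was 10.7% for chondrocyte Runx2 (6.16% after moving), 10.8% for osteoblast Runx2 (4.84%), 12.3% for Foxa2 (6.59%) and 22.0% for Jun (9.11%). In 3T3 cells it was 52.0% for Runx2 day 3 (38.0%) and 43.5% for the list named for GFP day 3 (14.8%). Overlapping intervals of 1 list counted as neighbours, and moving each peak on its own separates them. Merging such intervals took the list named for GFP day 3 from 16799 to 14179 peaks. Clustering of merged lists was not computed. By file order, 68.5% (66.1 to 70.8%) of the first 1539 peaks of the chondrocyte Runx2 list overlapped osteoblast Runx2, and 7.41% (6.20 to 8.82%) of the last 1539.

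Shared Runx2 peaks of osteoblasts overlapped Jun more often than osteoblast-only peaks, with an odds ratio of 1.92. Sites enriched in any precipitation might give such a pattern, and they would be seen in the GFP lists too. Without peaks overlapping a GFP list the odds ratio was 2.10 (1.88 to 2.35; 27.3% of 3372 shared and 15.2% of 4664 osteoblast-only peaks), which argues against this as the whole cause. One of these GFP lists has a crossed label. With the GFP day 0 list alone the odds ratio was 1.92 (1.75 to 2.12), and with the crossed lists exchanged it was 1.88 (1.59 to 2.23; 1217 shared and 3464 osteoblast-only peaks), so it rose only with the lists by name. Early position in the file, possibly a trace of peak strength, may carry a part. Compared within 10 equal parts of the osteoblast list, the odds ratio was 1.50 (1.37 to 1.65). These parts are coarse and follow the order of 1 list only. Whether position carries the whole therefore cannot be told. A biological link of Jun to sites that Runx2 holds in both cell types stays open as a hypothesis, since GFP background was measured in 3T3 cells and not in osteoblasts.

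The labels of 2 of the 3T3 lists were crossed, and the overlaps below went with the list names. In the uncrossed GFP day 0 list Jun overlapped more peaks (30.3%) than chondrocyte Runx2 did (18.3%), and in the uncrossed Runx2 day 3 list fewer (13.1% against 18.4%). The list named for Runx2 day 0 had a difference of -8.52 percentage points (18.7% against 27.2%), lower on 20 of 20 chromosomes, which argues against crossed list names. The list named for GFP day 3 had a difference of 10.2 points (25.0% against 14.7%), higher on 20 of 20, and so it is consistent with correct list names and crossed descriptions. Direct overlaps had the same order between the 2 crossed lists. The raw share alone does not mark a GFP list. In the longest list, Runx2 day 3, lay 56.4% of GFP day 0 peaks (60.3-fold over circular shifts). GFP day 0 peaks lay in the list named for GFP day 3 at 55.8% (183-fold over circular shifts) and in the longer list named for Runx2 day 0 at 47.0% (84.5-fold), and Runx2 day 3 peaks lay in the list named for Runx2 day 0 at 51.4% (95.6-fold) and in the list named for GFP day 3 at 15.9% (53.3-fold). Foxa2 overlapped 3.40% of the list named for Runx2 day 0 and 3.24% of Runx2 day 3, against 0.619% of the list named for GFP day 3 and 1.41% of GFP day 0. Each type of precipitation had 1 uncrossed list to compare with. Under the exchange the lists that resemble each other would be of the same day, and an effect of the day was not tested, so the assignment by list names remains a hypothesis.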
